A study of Mus musculus with 2 samples.

How the data were processed

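A single pool of cells from the stromal vascular fraction of epididymal fat was sequenced. Per the labels, wild-type and Mincle-deficient male mice had been on a high-fat diet for 15 weeks. Each suspension was stained with a hashtag antibody before pooling. A total of 20000 cells was loaded on a microwell capture system (BD Rhapsody), and cDNA and hashtags were amplified by a terminal-transferase method (TAS-Seq). The 2 deposited libraries are the transcripts and the hashtags of this pool. No label pairs a hashtag with a genotype or says how many mice stand behind a hashtag. The planned comparison of Mincle-deficient with wild-type cells was conditional on such a pairing and was not made.

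The transcript table deposited by the authors holds whole-number counts of 30084 genes in 15741 cells, and whether a count is a read or a molecule is not given in the sources used here. Per the submitters' processing notes, cutadapt 3.4, Bowtie2 2.4.2, R 3.6.3, R 4.1.2 and the GRCm38 genome were used, with no role stated for each. In the deposited counts, 68 genes, listed first in the table, have no value from 1 to 4, and the lowest value of such a gene lies between 5 and 68, so low values of these genes were set to 0 before deposit. Per the file headers, each cell name carries a hashtag or the word doublet, and the authors so assigned 15374 cells (97.7%) and named 367 doublets. The deposited hashtag table holds whole-number tag counts of 15 hashtags in 758098 barcodes. Its total is 38144503 tag counts, of which 72.0% fall in the cells of the transcript table.

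Cells were assigned to hashtags by a rule fixed before the data were examined. A cell needed at least 10 tag counts, with at least 75% of them from a single hashtag, and was called a multiplet where the second hashtag held over 25%. The rule assigned 11436 cells (72.7%), called 2462 multiplets (15.6%) and left 1843 cells (11.7%) unassigned. All 11436 cells had the same hashtag in the authors' calls. Cells needed at least 200 detected genes and at most 25% mitochondrial counts, which 184 cells failed. The 11281 cells kept were 2250 with hashtag A0309, 2250 with A0310, 2809 with A0311 and 3972 with A0312, with medians of 32916, 37406.5, 35785 and 34589.5 counts per cell. The hashtag multiplets were left out. Scrublet, run as an alternative, marked 2 cells, too few to have worked, so the top 5% of its scores were also left out in an added alternative.

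Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 with seed 1 gave the clusters. The 121 genes of 11 study lists were left out of the clustering, so that they could not define the classes compared. Clusters were named from 24 marker lists fixed before the data were examined. A name needed at least 3 markers detected in at least 25% of the cluster's cells and raised by a log2 difference of at least 1. For classes the reference was the lower quartile over clusters. For states it was the mean of the other clusters made within the class, those led by genes of another class left out. A cluster whose 10 leading genes held more markers of another class stayed unnamed. Macrophage-like and fibroblast-like cells were clustered again in the same way for their states. Sub-clusters led by genes of another class were kept within the class and left out in an added alternative. Of 303 listed genes, 9 were not analysed here. A table of gene names held 28967 (96.3%) of the symbols. Coordinates come from the GENCODE vM21 annotation of GRCm38.

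Each class was summed over its cells, per hashtag and in the pool, and the sums were scaled by the class's total over all genes to CPM. Cells are not replicates, and hashtags of unknown genotype are not replicates of a group, so no test was run and a rule of size was used. A gene was called higher in a class when the log2 ratio of CPM plus a pseudocount of 1 was at least 1 in size, with a single sign, in the pool and in every hashtag with at least 20 cells of both classes. Log2 ratios are on that scale, which understates the ratio of genes with low CPM. Intervals are 95% exact Poisson for summed counts and exact Clopper-Pearson for shares, and a count of 0 is given with the upper Poisson bound. They cover counting error only, and counts that are reads would not be independent molecules. The median of all genes at 5 CPM or more lay at -0.01 for macrophage-like over fibroblast-like, -0.15 for lipid-associated-like over resident-like and -0.03 for Dpp4-progenitor-like over preadipocyte-like cells.

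The genes named are Clec4e, Osm, Osmr and Tgfb1 in every comparison. From each list they are also the called members with the largest log2 ratios, up to 4, and the uncalled member with the highest CPM, at 5 CPM or more in either class. A gene that this rule names is not reported here. Cd36 was left out of the fibroblast state comparison because it is a marker of a state. The lists cover Mincle signalling, inflammatory cytokines and chemokines, the interleukin-6 family, the TGF-beta and PDGF axis, collagens, matrix glycoproteins and crosslinking, matrix proteases and inhibitors, lipid handling, lysosome and phagocytosis, macrophage growth factors, and immediate early genes.

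The size rule was tested on simulated counts drawn from the real sums, with 50 genes changed per fold. For macrophage-like against fibroblast-like cells (11195 genes) it called 60% of genes changed 3-fold, 96% of those changed 4-fold and 100% of those changed 8-fold. For the macrophage states (10151 genes) these shares were 50, 90 and 100%, and for the fibroblast states (11233 genes) 58, 90 and 100%. It called none of the genes changed 1.5-fold and none of the unchanged genes in any of the 3 comparisons. The spread between hashtags in these simulated counts was set in advance, alike for all genes, and not taken from the data. These shares therefore hold for that spread alone, and false calls are not excluded for real genes that vary more between hashtags. The hashtag rule was tested on 2000 simulated cells per setting. With 20 tag counts it assigned 99.8% of single cells correctly and called 93.0% of pairs multiplets, and with 500 tag counts both shares were 100%. The share of background tag counts in these simulated cells was set in advance and not taken from the data. Of the real fibroblast-like cells with under 50 tag counts, 92.1% failed the rule. The simulation therefore does not show how the rule performs on real cells with few tag counts.

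Alternatives planned before the data were examined were Leiden resolutions of 0.5 and 2.0 for the class shares, other cell filters, multiplets kept, Scrublet calls left out, other hashtag thresholds and study genes allowed in the clustering. For the comparisons they were a pseudocount of 5 CPM, the mean over cells of CPM, cells thinned to 10000 counts, TMM factors from edgeR 4.0.16, genes from 10 CPM alone, and each hashtag left out in turn. Alternatives added after seeing the data were the authors' hashtag calls, the top 5% of Scrublet scores left out, Leiden resolutions of 0.5 and 2.0 for the comparisons, and mixed sub-clusters left out. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.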

Results

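Single-cell RNA sequencing was carried out on the stromal vascular fraction of epididymal fat, the cells other than adipocytes that are released when fat is digested. The cells came from male C57BL/6J mice that were wild-type or lacked Mincle and had eaten a high-fat diet for 15 weeks. Mincle, the product of Clec4e, is a C-type lectin receptor of myeloid cells that binds mycobacterial glycolipid and material from dying cells. The series concerns signalling from macrophages to fibroblasts in the fibrosis of obese fat. Suspensions from both genotypes carried separate hashtag antibodies and were pooled, and the pool gave 2 libraries, 1 of transcripts and 1 of hashtags. The transcript library held 651658017 counts in 15741 cells, with a median of 34182 counts and 4503 genes per cell and a range of 6596 to 473807 counts. Per the labels, both libraries hold both genotypes, and no label pairs a hashtag with a genotype, so wild-type and Mincle-deficient cells were not compared. Hashtags of unknown genotype cannot serve as replicates of a group, so no test was run. Values are given for the pool, with the range over the 4 hashtags used, and intervals cover counting error only.

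Macrophage-like cells were the most abundant of the stromal vascular cells kept by the hashtag rule, followed in the pool by fibroblast-like and endothelial-like cells. Among 11281 cells kept with a single hashtag, 7781 were macrophage-like, and Adgre1, Cd68, C1qb and Csf1r met the naming rule in each of their clusters. Mrc1 did not meet it in clusters of 901 and 791 cells, nor did C1qa in the latter. Macrophage-like cells made up 69.0% of cells (95% exact binomial interval 68.1 to 69.8; 59.4 to 72.8 over hashtags). Fibroblast-like cells, with Pdgfra, Col1a1, Dcn and Lum, made up 9.40% (8.86 to 9.95; 8.33 to 10.7 over hashtags). Endothelial-like cells, with Pecam1, Cdh5 and Kdr, made up 8.31% (7.81 to 8.84; 6.09 to 9.87 over hashtags). They outnumbered fibroblast-like cells in A0309 (9.87 against 9.33%) and in A0311 (8.69 against 8.33%). Monocyte-like cells, with Ccr2, F13a1 and Fn1, made up 4.42% of the pool, and their share ranged from 2.79 to 9.42% over hashtags. T-cell-like cells made up 3.19%, and Nkg7 and Ccl5, genes of cytotoxic lymphocytes, were among their leading genes. Dendritic-cell-like cells made up 2.81% and mural-like cells, with Rgs5, Acta2 and Myh11, made up 2.75%. A mural-like cluster of 195 cells also had the endothelial genes Aqp1 and Plvap among its leading genes. A mesothelial-like cluster with Msln and Upk3b held 16 cells, or 0.142% (0.0811 to 0.230). The share of fibroblast-like cells depended on how hashtags were assigned. With the authors' own hashtag calls it was 25.8% and the macrophage-like share was 53.6%, while dendritic-cell-like cells were 1.07%. Under those calls a cluster of 150 cells with Clec9a and Flt3 among its leading genes stayed unnamed. A cluster of 145 cells with those leading genes had been named dendritic-cell-like above. The lower dendritic-cell-like share therefore comes at least in part from the naming. Monocyte-like cells were 0.495% with multiplets kept and 2.42% at Leiden resolution 2.0.

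**Figure D1:**
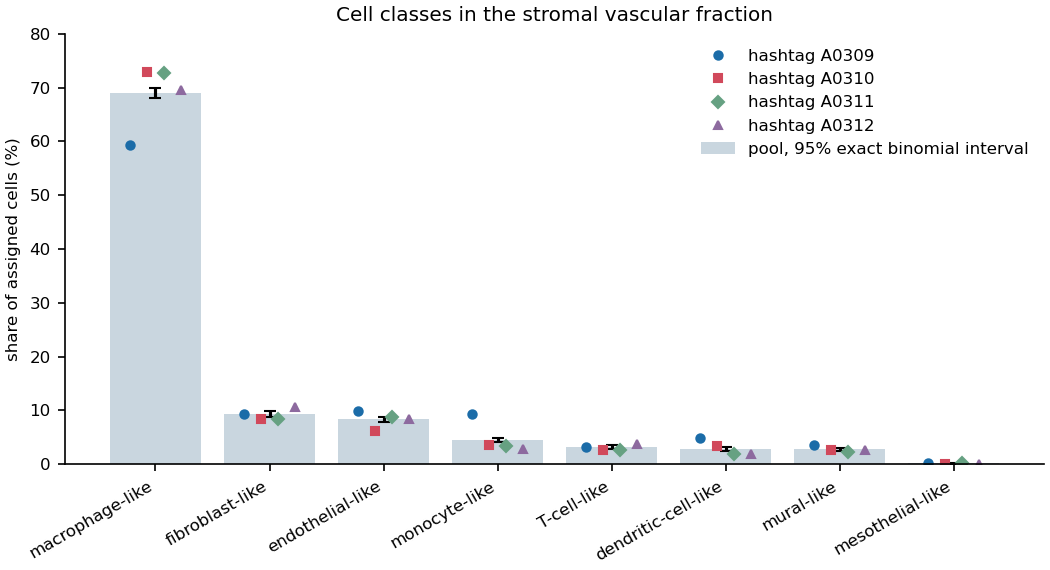
Share of cells per cell class in percent, for the pool (bars, with 95% exact binomial intervals) and for each of the 4 hashtags (points). Macrophage-like cells lie between 59.4 and 72.8% in every hashtag, and the monocyte-like share of hashtag A0309, 9.42%, lies above the other 3.

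Sub-clusters of the macrophage-like cells separated lipid-associated from resident macrophages, and sub-clusters of the fibroblast-like cells separated progenitors from preadipocytes. Lipid-associated-like cells, with Gpnmb and Mmp12 in each of their sub-clusters, numbered 1678, or 21.6% of macrophage-like cells (20.7 to 22.5). Only 3 to 5 markers of the state met the naming rule in a sub-cluster, and Trem2, Cd9, Lpl and Cd63 met it in none. Gpnmb was also among the leading genes of an unnamed sub-cluster of 690 cells, and Spp1 of an unnamed one of 608 cells. Resident-like cells, with Lyve1, Folr2, Cd163 and Cbr2, numbered 194, or 2.49% (2.16 to 2.86; 1.70 to 4.57 over hashtags). The fixed markers gave no state to 75.9% of macrophage-like cells. The number of resident-like cells was 78 at Leiden resolution 0.5 and 405 at 2.0, and that of lipid-associated-like cells 1356 and 2076. Cycling cells formed 2 macrophage-like clusters led by histone genes and by mitotic genes such as Ccnb1 and Plk1, and held 943 cells, or 12.1% of macrophage-like cells (11.4 to 12.9; 10.8 to 15.3 over hashtags). When macrophage-like cells were clustered again, histone genes led a sub-cluster of 536 cells and Cdc20 and Ccnb1 one of 299. A further one of 478 cells had Uhrf1, Rrm2 and Mcm5 among its leading genes. The share of cycling cells thus depends on the clustering, which the interval does not cover. Dpp4-progenitor-like fibroblasts, with Dpp4, Pi16, Cd55 and Sema3c, numbered 157, or 14.8% of fibroblast-like cells (12.7 to 17.1). Preadipocyte-like fibroblasts, with Fabp4 and Lpl, numbered 290, or 27.4% (24.7 to 30.1), and included a cycling sub-cluster of 38 cells. That sub-cluster was named on Fabp4, Lpl and Cd36 alone, and its leading genes held no marker of the state. Its median was 70615.5 counts, near the 72165.5 of a sub-cluster led by macrophage genes. With the authors' hashtag calls, a cycling sub-cluster of 61 cells had Lyz2 and Cd74 among its leading genes and stayed unnamed. Dpp4-progenitor-like and preadipocyte-like cells changed with the settings, to 206 and 140 cells at resolution 2.0. With the authors' hashtag calls they numbered 933 and 697 of 3922 fibroblast-like cells. Sub-clusters led by macrophage, monocyte or endothelial genes held 362 of the 1060 fibroblast-like cells, 34.2%, with a median of 60388 counts per cell against 38227 in the others. Only 0.784% of macrophage-like cells lay in sub-clusters led by genes of another class. With the authors' hashtag calls such sub-clusters held 443 of 3922 fibroblast-like cells, 11.3%, and 1.33% of macrophage-like cells. The share of fibroblast-like cells in them therefore depended on how hashtags were assigned.

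Over the pool, the levels of Clec4e and of the oncostatin M gene were highest in monocyte-like cells, and that of its receptor gene in stromal and vascular cells. Clec4e lies on chromosome 6 of GRCm38 from 123281789 to 123289870 on the minus strand and is annotated as protein-coding. Its level was 61.8 CPM, counts scaled to the total of the class, in monocyte-like cells (exact Poisson interval 57.7 to 66.2), 8.71 CPM in dendritic-cell-like cells and 4.99 CPM in macrophage-like cells (4.77 to 5.22). These values average wild-type and Mincle-deficient cells in proportions that the labels do not give. The Clec4e level in monocyte-like cells ranged from 0.384 to 129 CPM over hashtags, and A0309 gave 212 of the 499 cells. In A0312 it was 0.384 CPM in monocyte-like cells, from 1 count, with an upper Poisson bound of 2.14 CPM. Mural-like (1.06), endothelial-like (0.705) and macrophage-like cells (0.449) lay within that bound, so their order against monocyte-like cells is open there. T-cell-like (11.1) and dendritic-cell-like cells (8.79) lay above it. These rest on 27 counts in 3.31% of 151 cells and on 17 counts in 2 of 79 cells. The order of classes in the pool is therefore not shown for every hashtag. Osm, the gene of oncostatin M, a cytokine of the interleukin-6 family made by myeloid and T cells, lies on chromosome 11 from 4236420 to 4241026 on the plus strand. Osm reached 27.1 CPM in monocyte-like cells (24.4 to 30.0), 12.8 in T-cell-like cells (9.81 to 16.3) and 10.8 in macrophage-like cells (10.4 to 11.1), against 3.90 in fibroblast-like cells. T-cell-like cells lay above monocyte-like cells in A0309 (24.3 against 19.1 CPM) and below macrophage-like cells in A0310 and A0312, so their order is open. Osmr, the receptor subunit that binds oncostatin M, lies on chromosome 15 from 6813577 to 6874969 on the minus strand. Osmr was at 112 CPM in endothelial-like (107 to 117), 105 in fibroblast-like (102 to 108) and 98.4 in mural-like cells, and at 1.98 in macrophage-like cells. Tgfb1, which encodes the fibrogenic cytokine TGF-beta 1, lies on chromosome 7 from 25687002 to 25705077 on the plus strand. Tgfb1 was highest in monocyte-like (228 CPM) and macrophage-like cells (224 CPM), and lowest of the 7 larger classes in fibroblast-like cells (78.8 CPM).

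**Figure D2:**
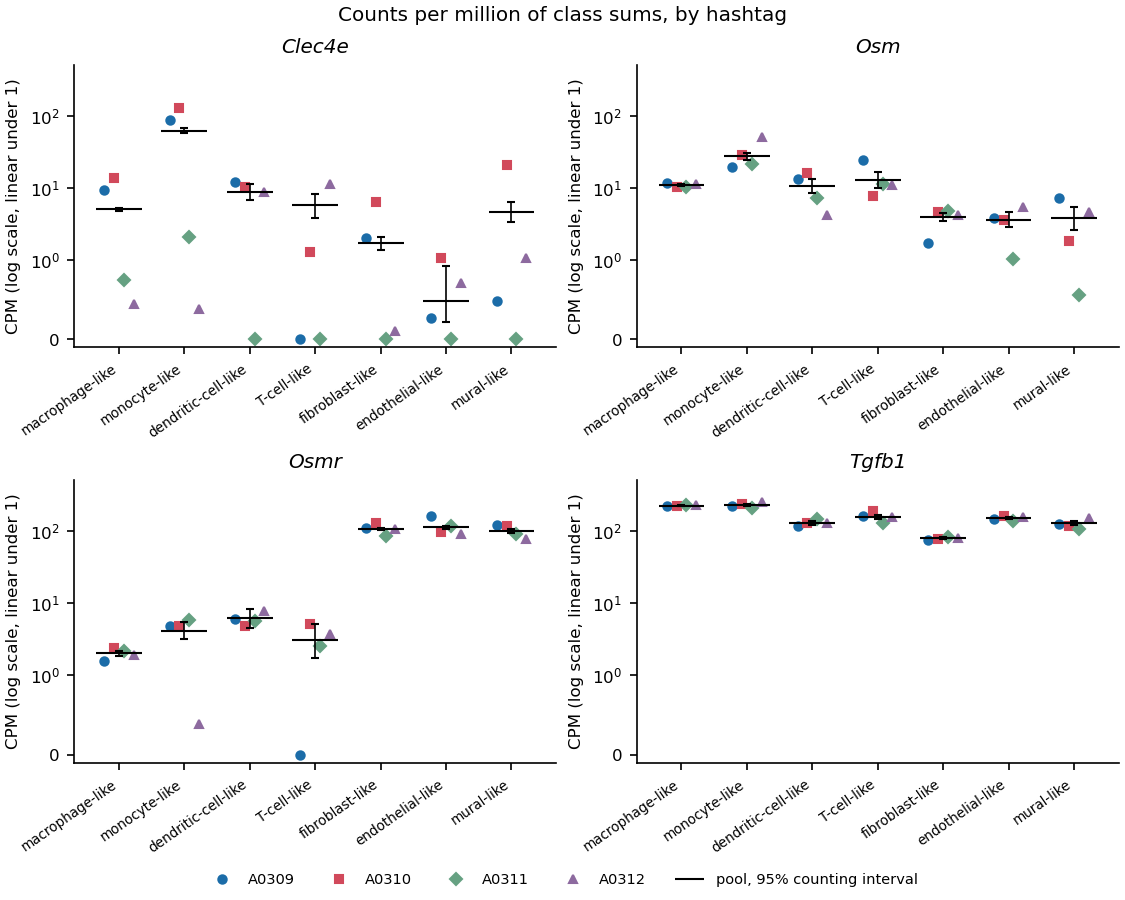
Level of Clec4e, Osm, Osmr and Tgfb1 in each cell class in CPM, with the pool's exact Poisson interval and a point for each hashtag. Osmr is at 1.98 CPM in macrophage-like and 105 CPM in fibroblast-like cells, and Tgfb1 at 224 and 78.8 CPM.

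The first comparison set macrophage-like against fibroblast-like cells and asked which cell type expresses each side of the exchange between them. Matrix genes, the receptor genes Osmr, Lifr and Il6st, and the macrophage growth factors Csf1 and Il34 were higher in fibroblasts. Several genes of Mincle signalling, lipid handling and the lysosome were higher in macrophages. Osmr had a log2 ratio of macrophage-like over fibroblast-like cells of -5.15 (-5.42 to -4.76 over hashtags), and Tgfb1 one of 1.49 (1.45 to 1.57). Osm had a log2 ratio of 1.27 and missed the size rule, a log2 ratio of at least 1 in the pool and every hashtag, because hashtag A0311 gave 0.98. Clec4e had a log2 ratio of 1.16 and was not called, with 1.77 in A0309, 1.02 in A0310, 0.80 in A0311 and 0.40 in A0312. In A0311 and A0312 its level was below 1 CPM in both classes, where the added 1 CPM holds the ratio near 0, so a lack of difference is not shown there. Of 121 listed genes, 25 were higher in macrophage-like cells, 56 were higher in fibroblast-like cells and 40 were not called.

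Of the genes of Mincle signalling, 4 of 7 were higher in macrophage-like cells and none was higher in fibroblast-like cells. They were Clec4d, a sister lectin receptor (91.9 against 22.5 CPM, log2 ratio 1.98), Syk, the kinase downstream of it (1.78), Fcer1g, the shared signalling chain (1.74), and the adaptor Card9 (1.56), which was not called at a pseudocount of 5 CPM or by the mean over cells. Bcl10, the next adaptor of that pathway, had a log2 ratio of 0.45. Among inflammatory cytokines and chemokines, 3 of 14 were higher in macrophage-like cells, among them Cxcl2 (2904 against 757 CPM) and Ccl3 (1.78), both leukocyte attractants. Il6 was higher in fibroblast-like cells (183 against 2.47 CPM, log2 ratio -5.73), as was the monocyte attractant Ccl7 (-2.54). Cxcl1 was not called (-0.67). In the interleukin-6 family, 5 of 12 members were higher in fibroblast-like cells and none in macrophage-like cells. Besides Osmr these included Socs3, the feedback inhibitor induced by these cytokines (738 against 77.0 CPM, -3.25), the shared receptor subunit Il6st (-1.74) and Lifr (-1.69, not called by the mean over cells). Stat3, which carries their signal, had a log2 ratio of -0.87. On the TGF-beta and PDGF axis, 2 of 12 genes were higher in macrophage-like and 7 in fibroblast-like cells. The latent TGF-beta binding proteins Ltbp4 (-5.86) and Ltbp1 (-5.42), the TGF-beta target Ccn2 (-5.46) and the co-receptor Tgfbr3 (-5.21) were higher in fibroblast-like cells, and Tgfbr1 was not called (0.93).

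All 11 fibrillar and associated collagens were higher in fibroblast-like cells. Col3a1 had 10618 CPM there against 5.18 in macrophage-like cells (log2 ratio -10.75), and Col6a2 (-9.11), Col6a1 (-9.00) and Col5a2 (-8.53) followed. All 14 matrix glycoprotein and crosslinking genes were higher there too, among them Sparc, a collagen-binding protein (-9.96), the microfibril gene Fbn1 (-9.17), Postn (-7.38) and the crosslinking enzyme Loxl1 (-6.80). Of 13 matrix proteases and inhibitors, 8 were higher in fibroblast-like cells and 1 in macrophage-like cells. The gelatinase Mmp2 (-8.61), the stromelysin Mmp3 (-7.05), the aggrecanase Adamts5 (-6.45) and the membrane protease Mmp14 (-5.86) had the largest ratios. Low values of Col3a1, Col5a2, Col6a1, Col6a2, Sparc, Fbn1, Postn, Mmp2 and Mmp3 are 0 in the deposited table, which bears on their level in macrophage-like cells, and the same holds for Cxcl2, Cd36, Ctsd, Ctsl and Ctss. Of 8 growth factors for macrophages and their receptors, 3 were higher in macrophage-like and 4 in fibroblast-like cells. The 4 were the chemokine Cxcl12 (354 against 7.77 CPM, -5.34), the macrophage growth factors Csf1 (288 against 6.61 CPM, -5.25) and Il34 (-4.37), and Cx3cl1 (-4.00). The receptor chain Csf2rb had a log2 ratio of 1.23 and was called only without hashtag A0311, at 1.32, and under some other settings. Leaving a hashtag out also removes its condition from the size rule, so calls gained that way here and below add no support.

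Lipid handling showed 7 of 10 genes higher in macrophage-like cells and none higher in fibroblast-like cells. The scavenger receptor Msr1 (log2 ratio 2.04), the fatty acid transporter Cd36 (4689 against 1272 CPM, 1.88), the sterol exporter Abcg1 (1.86) and the fatty acid binding protein Fabp5 (1.75) led, while the sterol carrier Npc2 was not called (0.52). Of 10 lysosomal and phagocytic genes, 5 were higher in macrophage-like and 1 in fibroblast-like cells. The proteases Ctss (1.89) and Ctsd (1.76), the surface receptor Cd84 (1.88) and progranulin, Grn (1.32), were higher in macrophage-like cells, and Ctsl was not called (0.76). Of 10 immediate early and dissociation genes, which digestion of tissue can induce, 4 were higher in fibroblast-like cells. These were Hspa1b (-2.28), Ier2 (-1.60), Egr1 (-1.59) and Jun (-1.42), and Fos was not called (-0.84). With the fibroblast-like sub-clusters led by other classes' genes left out, an alternative added after seeing the data, 33 genes were higher in macrophage-like and 56 in fibroblast-like cells, and the log2 ratio rose to 3.61 for Clec4d, 3.87 for Cd36 and 2.26 for Osm, which was then called. With the authors' hashtag calls besides, 34 and 60 genes were called, and the log2 ratio was 5.09 for Clec4d, 6.13 for Cd36 and 3.02 for Osm.

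**Figure D3:**
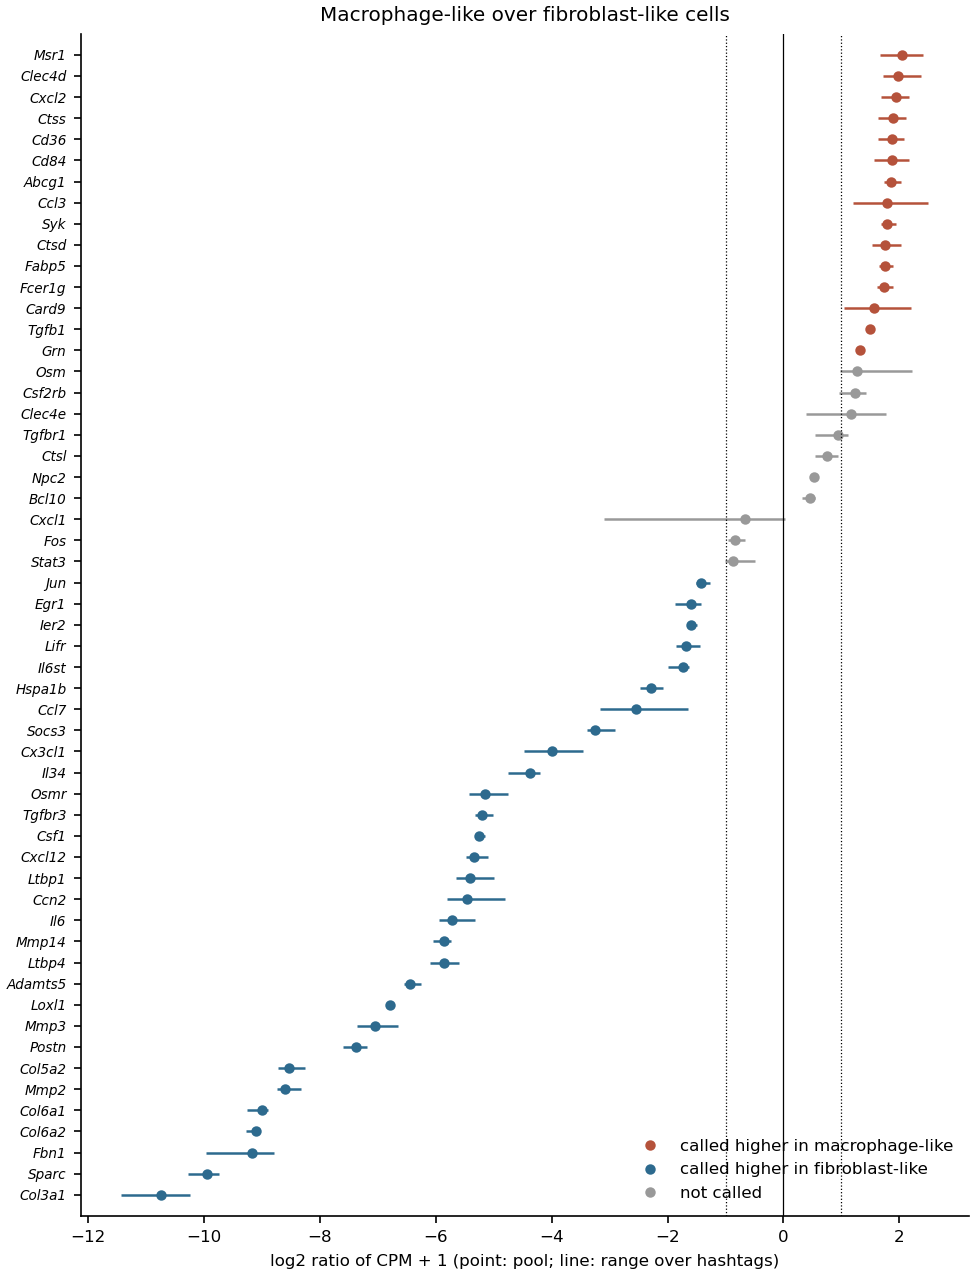
Log2 ratio of CPM plus 1, macrophage-like over fibroblast-like cells, for the genes named here in order of their ratio, in the pool (points) and as the range over hashtags (lines). Col3a1 lies at -10.75, Osmr at -5.15, Osm at 1.27 and Tgfb1 at 1.49.

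The second comparison set lipid-associated-like against resident-like macrophages, the former being cells that gather around dying adipocytes in obese fat. The lipid handling genes Fabp5, Cd36, Lipa and Soat1, the lysosomal proteases Ctsl and Ctsd, and Mmp19 were higher in lipid-associated-like cells, though none of them was called with clusters made at Leiden resolution 2.0. The chemokines Ccl2, Ccl4 and Ccl7, the receptors Lifr, Il6ra and Tgfbr2, and several immediate early genes were higher in resident-like cells, of which Ccl2, Il6ra, Fos and Atf3 were not called at that resolution either. Mmp19, a matrix metalloprotease, had the largest ratio toward lipid-associated-like cells (195 against 22.9 CPM, log2 ratio 3.03), and Ccl7 the largest toward resident-like cells (12.2 against 424 CPM, -5.01). Low values of Cd36, Ctsl and Ctsd are 0 in the deposited table. Resident-like cells had a median of 21322.5 counts, against medians of 56402 to 73117 in the lipid-associated-like sub-clusters. Zeroed values may therefore weigh more on resident-like cells, and whether they enlarge the ratios of these genes was not tested. Tgfb1 (211 and 189 CPM, log2 ratio 0.16) and Clec4e (4.03 and 3.25 CPM, 0.24) were not called. Clec4e was at 0.744 CPM in all macrophage-like cells of A0311 and 0.449 CPM in those of A0312. At such levels the added 1 CPM holds the ratio near 0, so a lack of difference is not shown there. Osm was at 5.14 CPM in lipid-associated-like (4.73 to 5.57) and 21.4 CPM in resident-like cells (17.4 to 26.1). Its log2 ratio of -1.87 was not called, because hashtag A0310 gave 0.24 where the other 3 lay between -2.18 and -2.09, and without A0310 it was called at -2.15. Among alternatives added after seeing the data, Osm was called with the authors' hashtag calls. It was also called at Leiden resolution 0.5, where only 2 hashtags entered the rule. Osmr was at 1.85 and 1.08 CPM and was not called (0.45). Of 121 genes, 12 were higher in lipid-associated-like cells, 20 in resident-like cells and 89 were not called.

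Lipid handling had 4 of 10 genes higher in lipid-associated-like cells and 1 higher in resident-like cells. The former included Fabp5 (1131 against 224 CPM, log2 ratio 2.33), Cd36 (1.67), the acid lipase Lipa (1.40) and the cholesterol esterifying enzyme Soat1 (1.38, not called by the mean over cells), and the lipid droplet gene Plin2 was not called (1.42), except without hashtag A0312 (1.70) and under other settings. Of lysosomal and phagocytic genes, 3 of 10 were higher in lipid-associated-like cells, namely Ctsl (4551 against 1037 CPM, 2.13), Ctsd (1.48) and Cd84 (1.31, not called by the mean over cells or without the top Scrublet scores). Mertk, a receptor for the uptake of dying cells, was higher in resident-like cells (-1.74, not called at Leiden resolution 2.0), and Ctss was not called (1.18), except without hashtag A0312 (1.26) and under other settings. Of the proteases and inhibitors, 2 of 13 were higher in lipid-associated-like cells, Mmp19 and the gelatinase Mmp9 (1.97), and the inhibitor Timp2 was not called (-0.65). Mmp9 was not called at a pseudocount of 5 CPM, in thinned cells, without Scrublet doublets, with only genes from 10 CPM or with the study genes in the clustering. Among inflammatory genes, 5 of 14 were higher in resident-like cells, led by the chemokines Ccl7, Ccl4 (-3.39), Ccl2 (72.2 against 490 CPM, -2.75) and Ccl3 (-1.83), and 1 was higher in lipid-associated-like cells. Ccl3 was not called by the mean over cells or in thinned cells. Cxcl2 had a log2 ratio of 0.48. In the interleukin-6 family, 3 of 12 genes were higher in resident-like cells, Lifr (-4.05), Socs3 (37.7 against 371 CPM, -3.27) and Il6ra (-1.79). The interleukin-11 receptor gene Il11ra1 (1.96, not called with the authors' hashtag calls) was among 2 higher in lipid-associated-like cells, and Stat3 was not called (-1.01).

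On the TGF-beta and PDGF axis, the growth factor Pdgfc (-2.99) and the receptor Tgfbr2 (49.1 against 243 CPM, -2.28) were the 2 of 12 genes higher in resident-like cells. Of the growth factors and their receptors, Cxcl12 was the 1 of 8 that was called (-1.83, higher in resident-like cells), and Csf2ra was not called (0.91). Cxcl12 was not called at a pseudocount of 5 CPM, by the mean over cells or in thinned cells. Of the immediate early and dissociation genes, 7 of 10 were higher in resident-like cells, among them Egr1 (-2.36), Ier2 (-2.35), Hspa1a (-2.15) and Jun (-2.13), and Dusp1 was not called (-0.86). None of the 7 genes of Mincle signalling, 11 collagens and 14 matrix glycoprotein and crosslinking genes was called. Fcer1g had a log2 ratio of -0.39, P4ha1, a collagen-modifying enzyme, 0.27, and Col3a1 ranged from -4.38 to 2.58 over hashtags and was called at 2.22 without hashtag A0311. TMM scaling moved the median log2 ratio over all genes up by 0.44 and gave 18 genes higher in lipid-associated-like and 15 in resident-like cells, with Ccl3, Cxcl12, Fos and Atf3 no longer called. With clusters made at Leiden resolution 2.0, no gene was called higher in lipid-associated-like cells and 13 were called higher in resident-like cells, without Ccl3 and Cxcl12, while resolution 0.5 gave 22 higher in lipid-associated-like cells, but there only 2 hashtags held enough resident-like cells for the size rule, so that number is not comparable.

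**Figure D4:**
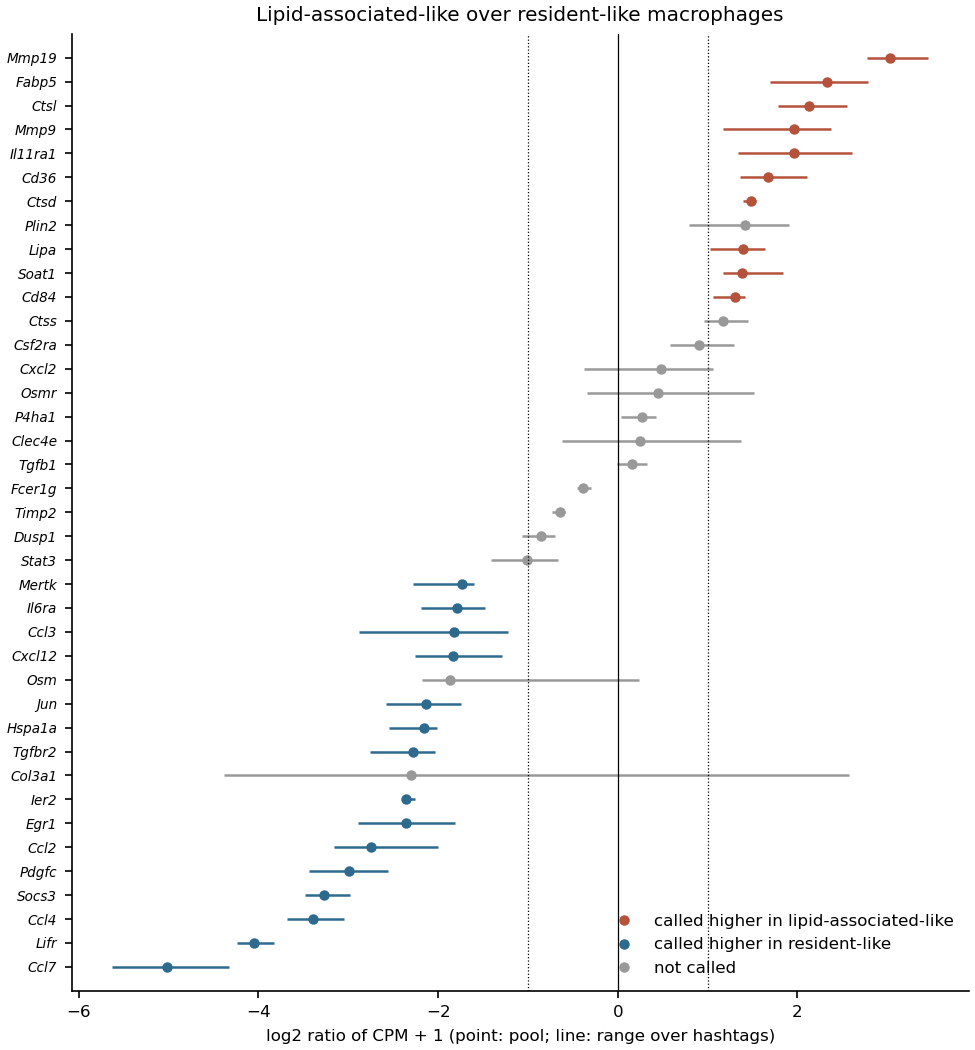
Log2 ratio of CPM plus 1, lipid-associated-like over resident-like macrophages, for the genes named here in order of their ratio, in the pool (points) and as the range over hashtags (lines). Mmp19 lies at 3.03 and Ccl7 at -5.01, while Tgfb1 lies at 0.16.

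The third comparison set Dpp4-progenitor-like against preadipocyte-like fibroblasts, the former being progenitors that lie in the connective tissue around fat lobules. The metalloprotease inhibitor Timp3 was higher in Dpp4-progenitor-like cells (820 against 194 CPM, log2 ratio 2.08), as were Timp2 (6966 against 2405 CPM, 1.53), Fbn1 (4196 against 1611 CPM, 1.38) and Col14a1 (1.35). The matrix glycoprotein Tnc (2.70 against 72.1 CPM, -4.31), Mmp3 (-3.64), the collagen maturation protein Pcolce (366 against 1335 CPM, -1.86) and Col6a3 (-1.64) were higher in preadipocyte-like cells. With clusters made at Leiden resolution 2.0, Timp2, Fbn1, Col14a1, Tnc and Mmp3 were no longer called, and Col14a1 was not called by the mean over cells either. Osmr was at 69.9 CPM in Dpp4-progenitor-like (63.6 to 76.8) and 153 CPM in preadipocyte-like cells (147 to 160), and its log2 ratio of -1.12 was not called, since it ranged from -1.47 to -0.69 over hashtags. Tgfb1 was at 26.5 and 54.1 CPM and was called only without hashtag A0311, at a log2 ratio of -1.07. Clec4e was not counted in Dpp4-progenitor-like cells, which allows up to 0.585 CPM, and was at 1.36 CPM in preadipocyte-like cells. Osm was not counted in Dpp4-progenitor-like cells either and was at 2.18 CPM in preadipocyte-like cells. Neither gene was called, except Osm without hashtag A0310. Clec4e was not counted in any fibroblast-like cell of A0311, so the size rule could not be met for it there.

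Of 120 listed genes, 6 were higher in Dpp4-progenitor-like cells, 10 in preadipocyte-like cells and 104 were not called. The collagens gave 1 gene each way of 11, with Col3a1 not called (-0.93). The matrix glycoprotein and crosslinking genes gave 1 of 14 higher in Dpp4-progenitor-like and 2 in preadipocyte-like cells, with Sparc not called (-1.08). The proteases and inhibitors gave 2 of 13 higher in Dpp4-progenitor-like and 1 in preadipocyte-like cells, with Mmp2 not called (0.31). The interleukin-6 family and the lysosomal genes gave 1 gene each that was higher in Dpp4-progenitor-like cells. Socs3 was higher there (1128 against 464 CPM, 1.28), as was the receptor tyrosine kinase Axl (1.24), and Il6st had a log2 ratio of 0.19. Cx3cl1, a membrane-bound chemokine, was higher in preadipocyte-like cells (-2.70, not called at Leiden resolution 2.0), whereas Csf1 was not called (0.11). The lipid droplet gene Plin2 was higher in preadipocyte-like cells (117 against 452 CPM, -1.94), though not at Leiden resolution 2.0, where it was at 0.29, and Npc2 was not called (0.02). None of the TGF-beta and PDGF genes was called, and Ltbp4 had a log2 ratio of 1.05. None of the immediate early genes was called either, and Fos had a log2 ratio of 0.52.

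Genes of myeloid cells were also counted higher in preadipocyte-like cells, 2 of the 7 Mincle signalling genes, 1 of the 14 inflammatory genes and 1 of the 10 lysosomal genes. They were Clec4d (0.476 against 11.1 CPM, -3.03), Cxcl2 (-3.03), Ctss (-2.51) and Fcer1g (-2.05). Whether the cycling sub-cluster of the preadipocyte-like cells gave rise to these counts was not tested. The direction of these myeloid genes did not hold under other settings. With the authors' hashtag calls, Cxcl2 was at 1.55, Fcer1g at 0.02 and Ctss at -0.07, Socs3, Axl and Plin2 were not called, and at Leiden resolution 2.0 Clec4d was at 1.77. Bcl10 (-0.02), Cxcl1 (0.60) and Ctsl (-0.18) were not called. Without hashtag A0309, Sparc was called at -1.18, and leaving it out gave 16 genes higher in preadipocyte-like cells where 10 were called, under a rule that then asked for 3 hashtags in place of 4. At Leiden resolution 2.0, 12 genes were higher in Dpp4-progenitor-like cells, of which 1 was among the 6 called here, and 8 were higher in preadipocyte-like cells, of which 2 were among the 10.

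**Figure D5:**
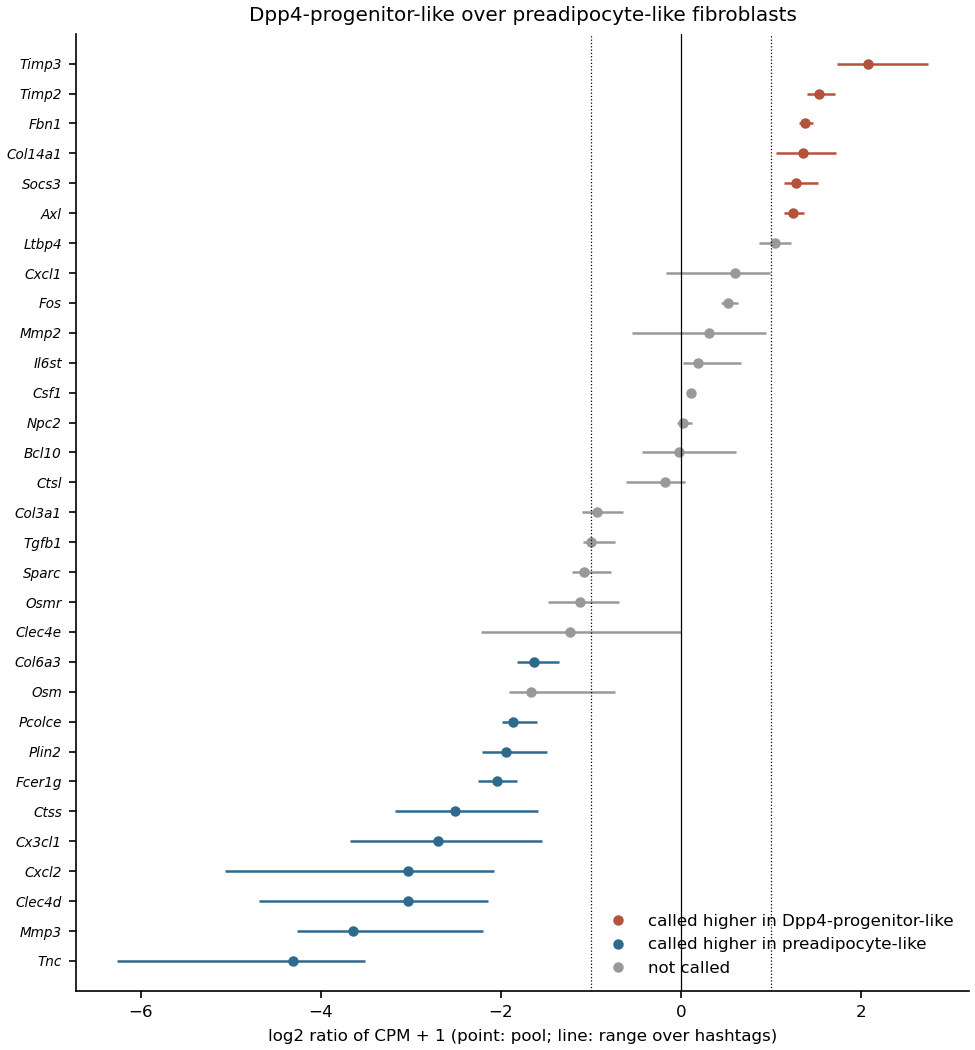
Log2 ratio of CPM plus 1, Dpp4-progenitor-like over preadipocyte-like fibroblasts, for the genes named here in order of their ratio, in the pool (points) and as the range over hashtags (lines). Timp3 lies at 2.08 and Tnc at -4.31, while Col3a1 lies at -0.93.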

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

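Chosen after results were seen were the tests on failing at like tag counts, on MHC class I transcripts, on matched levels of matrix genes, on total counts of sub-clusters and on macrophage markers across classes, whereas the others were written before their values were seen. Over the 4 hashtags, 17 of 175 sets of 4 values had a highest or lowest value far from the other 3, where chance sets apart about 1 in 20, or 8.75. The genotypes of the hashtags are not known, so no biological explanation was tested.

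Fibroblast-like cells, named among all cells that passed the cell filter, failed the fixed hashtag rule far more often than other cells. Of them 76.1% failed (interval 74.8 to 77.4), against 40.7% of mural-like, 18.0% of endothelial-like and 6.27% of macrophage-like cells, with medians of 38, 188, 505 and 1293.5 tag counts per cell. Whether cells of different suspensions under one barcode add to the failing could not be decided from total counts. Fibroblast-like multiplets had 0.917 times the median total count of the other fibroblast-like cells (0.858 to 0.981 over hashtags). Endothelial-like multiplets had only 1.25 times that of the other endothelial-like cells, so the rise looked for is small. Of the fibroblast-like cells kept by the rule, 34.2% lay in sub-clusters led by genes of other classes. Their median was 60388 counts against 38227 in the others, which may raise the median compared with. Total counts therefore neither favour nor exclude this source of the failing. Few tag counts may account for part of it, because 10.7% of the fibroblast-like cells with at least 200 tag counts failed (3.37 to 17.2 over hashtags), but at 50 to 200 tag counts 70.6% failed, against 50.3% of mural-like and 27.2% of macrophage-like cells, and in narrow bins, which held 168 of the 1026 fibroblast-like cells, 49.4 against 26.5% of macrophage-like cells. Less MHC class I transcript cannot be told apart from it, since the summed CPM of H2-K1, H2-D1 and B2m was 0.480 times that of endothelial-like cells (0.464 to 0.532 over hashtags), which straddles the bound set for that explanation.

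The 7 matrix genes of the lists whose low values are 0 in the deposited table had a median log2 ratio of macrophage-like over fibroblast-like cells of -9.11, against -5.96 for the other 18. Setting low values of those 18 genes to 0 in the same way moved their median by 1.69 further from 0 (1.504 to 1.83 over hashtags), to -7.65. The zeroed values may therefore enlarge these ratios. Higher levels in fibroblast-like cells cannot be told apart from it for the rest, since the highest of the 18 had 975 CPM there, below the lowest of the 7, so no level is shared.

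Macrophage markers were counted in fibroblast-like cells, most in the sub-clusters led by genes of other classes. A macrophage and a fibroblast under one barcode may account for those led by macrophage or monocyte genes, whose median total count was 1.69 times that of the other fibroblast-like cells (1.42 to 1.83 over hashtags). Free RNA alike in all barcodes was weighed for the remainder, where the counts per cell of 5 macrophage markers differed by 1.74 times between the remaining fibroblast-like (19.4), endothelial-like (24.5), mural-like (20.8) and T-cell-like cells (14.1). That ratio ranged from 1.60 to 3.48 over hashtags, so free RNA and its absence cannot be told apart.

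The monocyte-like share was 9.42% in hashtag A0309 and 2.79 to 3.64% in the other 3. Clec4e was at 11.1 CPM in T-cell-like cells of A0312 and at 20.9 CPM in mural-like cells of A0310, each above the other 3, but these rest on 3.31% of 151 and 5.08% of 59 cells. Clec4d, the sister receptor gene, was at 176 CPM in macrophage-like cells of A0310 (60.8 to 75.8 in the others), at 52.5 CPM in its fibroblast-like cells (11.3 to 16.2) and at 23.4 CPM in endothelial-like cells of A0312 (10.0 to 11.3). Osm was at 1.68 CPM in fibroblast-like cells of A0309 (4.20 to 4.65 in the others). The log2 ratio of macrophage-like over fibroblast-like cells stood apart for Stat3 in A0311 (-0.50, others at -0.98 or below). The log2 ratio of lipid-associated-like over resident-like cells stood apart for Fcer1g in A0312 (-0.30), Osm in A0310 (0.24), Soat1 in A0309 (1.84) and Hspa1a in A0309 (-2.55). The log2 ratio of Dpp4-progenitor-like over preadipocyte-like cells stood apart for Cxcl2 (-5.06) and Sparc (-0.77) in A0309, Osm (-0.74) and Mmp3 (-2.20) in A0310 and Il6st (0.67) in A0311. Of the 17 values, 6 were from A0309, 6 from A0310, 2 from A0311 and 3 from A0312.

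Tag counts also appeared where no cell was assigned. Unused hashtags A0308 and A0313 had 2063 and 2452 tag counts, the other 9 unused hashtags together had 779, and barcodes outside the cells of the transcript table held 10665626.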

How the results depend on the processing

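The authors' hashtag calls, the top 5% of Scrublet scores left out, mixed sub-clusters left out and, for the comparisons, Leiden resolutions 0.5 and 2.0 were chosen after seeing the data. For each change given here, the cause was not tested.

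Keeping multiplets gave 57.7% macrophage-like, 20.6% fibroblast-like, 0.495% monocyte-like, 2.28% dendritic-cell-like, 2.86% T-cell-like and 3.14% mural-like cells. The authors' hashtag calls gave 53.6% macrophage-like, 25.8% fibroblast-like, 7.56% endothelial-like, 3.71% mural-like, 2.63% T-cell-like and 1.07% dendritic-cell-like cells. Under those calls 0.987% of cells stayed unnamed, in a cluster with Clec9a and Flt3 among its leading genes. Leaving out the top 5% of Scrublet scores gave 69.96% macrophage-like, 8.21% fibroblast-like, 7.75% endothelial-like and 5.34% monocyte-like cells. Leiden resolution 0.5 gave 5.48% monocyte-like and 1.46% dendritic-cell-like cells. Resolution 2.0 gave 2.42% monocyte-like, 1.87% T-cell-like, 7.64% endothelial-like and 2.36% mural-like cells. Monocyte-like cells were 3.93% with no filter on cells and 4.97% with at least 1000 genes and at most 10% mitochondrial counts. Leaving out each hashtag in turn gave 67.8 to 71.4% macrophage-like, 3.18 to 5.31% monocyte-like, 2.30 to 3.26% dendritic-cell-like, 2.86 to 3.38% T-cell-like, 8.69 to 9.75% fibroblast-like and 7.93 to 8.87% endothelial-like cells. The number of assigned cells was 8821 with 90% and 20 tag counts, 12893 with 60% and 5 tag counts, and 15374 by the authors' calls.

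The direction of every named gene called was kept between macrophage-like and fibroblast-like cells under the alternatives run. Of the values of named genes under them, 930 stayed called or uncalled as before, 18 gained a call and 3 lost it, Card9 at a pseudocount of 5 CPM and by the mean over cells, and Lifr by the mean over cells. The 25 genes higher in macrophage-like cells were all kept with the authors' calls and with mixed sub-clusters left out. TMM factors shifted the median log2 ratio over all genes by 0.168 and gave 30 and 54 calls. Between lipid-associated-like and resident-like cells, 535 values stayed called or uncalled, 15 gained a call and 31 lost it. Besides resolution 2.0, alternatives ended calls of Ccl3, Mmp9, Cxcl12, Soat1, Cd84, Il11ra1, Fos and Atf3, among others. Genes higher in lipid-associated-like cells numbered 22 at resolution 0.5, where only 2 hashtags entered the rule, and 0 at 2.0, and those higher in resident-like cells 13 at 2.0. Col3a1, not called in the pool at -2.30, ranged from -2.94 to 2.22 with each hashtag left out and was called at 2.22 without A0311.

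Between Dpp4-progenitor-like and preadipocyte-like cells, 390 values stayed called or uncalled, 9 gained a call and 23 lost it, and 10 changed direction. Besides resolution 2.0, alternatives ended calls of Clec4d, Fcer1g, Ctss, Cxcl2, Socs3, Col14a1, Plin2 and Axl. Genes higher in Dpp4-progenitor-like cells numbered 12 at resolution 2.0. Genes higher in preadipocyte-like cells numbered 12 to 16 with each hashtag left out, which drops its condition from the rule. At resolution 2.0, Clec4d was at 1.77, Fcer1g at 2.67, Cxcl2 at 4.56, Plin2 at 0.29 and Ctss at 3.56. With the authors' calls, Fcer1g was at 0.0225 and Cxcl2 at 1.55, and with the top Scrublet scores left out Fcer1g was at 0.43, Cxcl2 at 1.29 and Ctss at 0.57. Resolution 0.5 gave no value for this comparison.

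The planned comparison of genotypes was not made, so its alternatives of DESeq2, no low-count filter, a replicate block and replicates left out were not run. No paired analysis was possible because the labels give no replicate numbers and no hashtag's genotype. Hashtags held 21 to 71 Dpp4-progenitor-like and 37 to 61 resident-like cells, and 3-fold changes were called for 50 to 60% of simulated genes, so an uncalled gene is not shown to be unchanged.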

Other observations

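Chosen after results were seen were the genes and classes given here. Il6 was at 193 CPM in mural-like and 183 CPM in fibroblast-like cells. Pdgfb, the ligand that recruits mural cells, was at 236 CPM in endothelial-like cells, and Cxcl12 at 696 CPM there. Endothelial-like cells also held the highest Cd36 level of the classes, 7151 CPM, and 467 CPM of the receptor chain Csf2rb. Postn was at 1603 CPM in mural-like cells, above its 1441 CPM in fibroblast-like cells, and Sparc at 9468 CPM in mural-like and 7907 CPM in endothelial-like cells. Timp3 was highest in mural-like cells (2501 CPM), as was the macrophage growth factor Il34 (79.1 CPM). Dendritic-cell-like cells had the highest Il1b level (457 CPM), ahead of monocyte-like cells (257 CPM), and T-cell-like cells the highest Ccl5 level (2205 CPM).

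Macrophage-like cells also held a cluster of 51 cells led by interferon-induced genes, among them Rsad2, Cxcl10, Ifit1 and Mx1. An F3- or Clec11a-like fibroblast sub-cluster held 15 cells, 1.42% of fibroblast-like cells.

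Clec4e levels differed widely between hashtags whose genotype the labels do not give. Over all cells the values fell into separate clusters, with A0309 and A0310 high and A0311 and A0312 low, at 12.8 CPM in A0309, 15.1 in A0310, 0.640 in A0311 and 0.675 in A0312. In monocyte-like cells they were 86.3, 129, 2.06 and 0.384 CPM in the same order, and in macrophage-like cells 9.10, 13.7, 0.744 and 0.449 CPM. In dendritic-cell-like cells they were 12.0, 10.2, 0 and 8.79 CPM, the last from 17 counts in 2 of 79 cells. Over all cells, the share with a Clec4e count was 8.76, 11.6, 1.07 and 1.13%. No genotype was read from these values, and no comparison was made between hashtags on their basis.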
